A study of Homo sapiens with 8 samples.

How the data were processed

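RNA was measured in 8 libraries of DU145, an established epithelial prostate carcinoma cell line derived from a brain metastasis. Per the labels, 4 libraries came from control cells and 4 from cells with exogenous SOX11 expression. Total RNA was extracted with an automated Maxwell RSC simplyRNA kit and poly(A) libraries were made with a TruSeq Stranded mRNA kit, per the labels' protocols. Poly(A) selection favours polyadenylated transcripts, so replication-dependent histone genes, whose main transcripts lack a poly(A) tail, are measured only in part. Per the submitters' processing notes, the tools cutadapt, FastQC and STAR (version 2.7.0e) and the genome build GRCh38 were used. Their roles, the read counter, its strand setting and the annotation release are not given in the sources used here.

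The authors deposited 1 table of raw counts per Ensembl gene with a column for each library and no normalization. The table held 32066 genes, each with a count in at least 1 library. All 8 columns were matched to samples by name and no column was left over. Total counts ran from 14641250 to 18706095 per library. Gene symbols came from a table of Ensembl names, which matched 32053 of the 32066 identifiers. Coordinates are 1-based positions on GRCh38 from the GENCODE 29 annotation, which may differ from the annotation the authors counted on.

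From these counts, genes were filtered with filterByExpr (minimum count 10, group given), which left 15665 genes. Libraries were scaled with TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit) in R 4.3.3, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p below 0.05. Log2 fold changes are SOX11 minus control, and their standard error (SE) was derived from the coefficient and its F statistic. CPM values are TMM-scaled values computed from the deposited counts, given as mean ± SD over 4 libraries. Floors for a count of 0 were set at 3 counts over the control group and cover counting error only.

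Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera compares a list with all other genes. The same test with a correlation estimated from the data, and fry, which asks whether a list's genes move one way on balance, were run beside it. Lists with fewer than 3 tested members were not tested. The 35 lists cover mesenchymal, epithelial, basal, neuronal, neuroendocrine, androgen receptor and SOX genes, cell cycle, interferon, antigen presentation, NF-kB, adhesion, matrix, protease, motility, axon guidance, WNT, NOTCH, TGF-beta, growth factor, hypoxia, cholesterol, stress response, p53, oxidative stress, ribosome biogenesis, oxidative phosphorylation, ribosomal protein, mitochondrial, histone and immediate early genes, and markers of fibroblasts, blood cells, endothelium and the embryonic kidney line HEK293. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined.

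Genes were named by that rule. SOX11 came first. Then came the 15 called genes with the largest increase and the 15 with the largest decrease, among genes with a mean of at least 1 CPM and no overlap between the groups. Up to 4 called members of each list with the smallest adjusted p followed. For a list with no called member, the most abundant member was named. Among the genes ranked by decrease, 5 without a symbol were passed over and 0 among those ranked by increase. CDH1 and VIM were added after their values were seen. Some genes taken by the rule are not reported here.

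The scripts were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 genes changed by known folds in each of 5 simulations. For SOX11 overexpression versus control, edgeR on 15473 genes recovered 61.0% of the 1.25-fold changes, 77.2% of the 1.5-fold, 94.6% of the 2-fold and 100% of the 4-fold changes. Unchanged genes made up 7.01% of its calls, above the nominal 5%. These shares count only genes that passed the filter. Each simulation changed 200 genes, while 3130 were called in the data, so the shares may not carry over. Camera on the same 15473 genes called the shifted list in 5 of 5 simulations and 0 of 100 unchanged lists. Fry called 2 of the 100. These simulated genes were independent of one another, so the simulation does not show how camera behaves on correlated genes.

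Alternatives were DESeq2 median-of-ratios factors (RLE), upper quartile scaling, library sizes without SOX11, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom, a test against a 2-fold change (glmTreat), the replicate number as a block, and each library left out in turn. Offsets for transcript length and GC content were added after the data were seen.

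The libraries were checked for repeated deposits by a chi-square test of their counts. Within groups, the statistic per degree of freedom was 1.43 to 3.28 over 12 pairs, so each pair differed by more than sampling noise and all libraries were kept. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No batch is given in the labels. CORO1A, the gene named for a list with no called member, was not checked for overlap. Of the 149 called genes taken by the rule, 148 had coordinates, and 35 of them overlap an annotated gene on the opposite strand and 18 on the same strand. Counts of such genes are uncertain because the strand setting of the counting is not given in the sources used here. Near-identical copies such as TMSB15A, HLA genes, histone genes and ribosomal protein genes with their pseudogenes are uncertain because a read can match several copies, and how such reads were counted is not given in the sources used here.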

Results

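Gene expression was profiled by RNA sequencing in DU145 prostate cancer cells with exogenous SOX11 (4 libraries) and in control DU145 cells (4 libraries). SOX11 is a SOX-family transcription factor of the developing nervous system. The comparison asks which transcripts change when SOX11 is expressed in this line. Total counts were 14641250 to 18706095 in the control libraries and 15309037 to 16740516 in the SOX11 libraries. The first principal component held 38.6% of the variance and separated the groups. Mitochondrial genes took 8.55% to 9.24% of counts in control and 8.73% to 9.35% in SOX11 libraries.

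SOX11 (ENSG00000176887, chromosome 2, 5692667 to 5701385, plus strand, 1 exon, GRCh38) had 0 counts in all 4 control libraries and 303 to 317 counts in the SOX11 libraries. Its level there was 19.2 ± 0.943 CPM (SD, n = 4). Against the 3-count floor over the control group, 0.0475 CPM, this was at least 404-fold higher (edgeR adjusted p = 2.11e-21). The counts do not separate the introduced sequence from the endogenous gene, and an annotated gene on the same strand, AC108025.2, overlaps it.

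**Figure D1:**
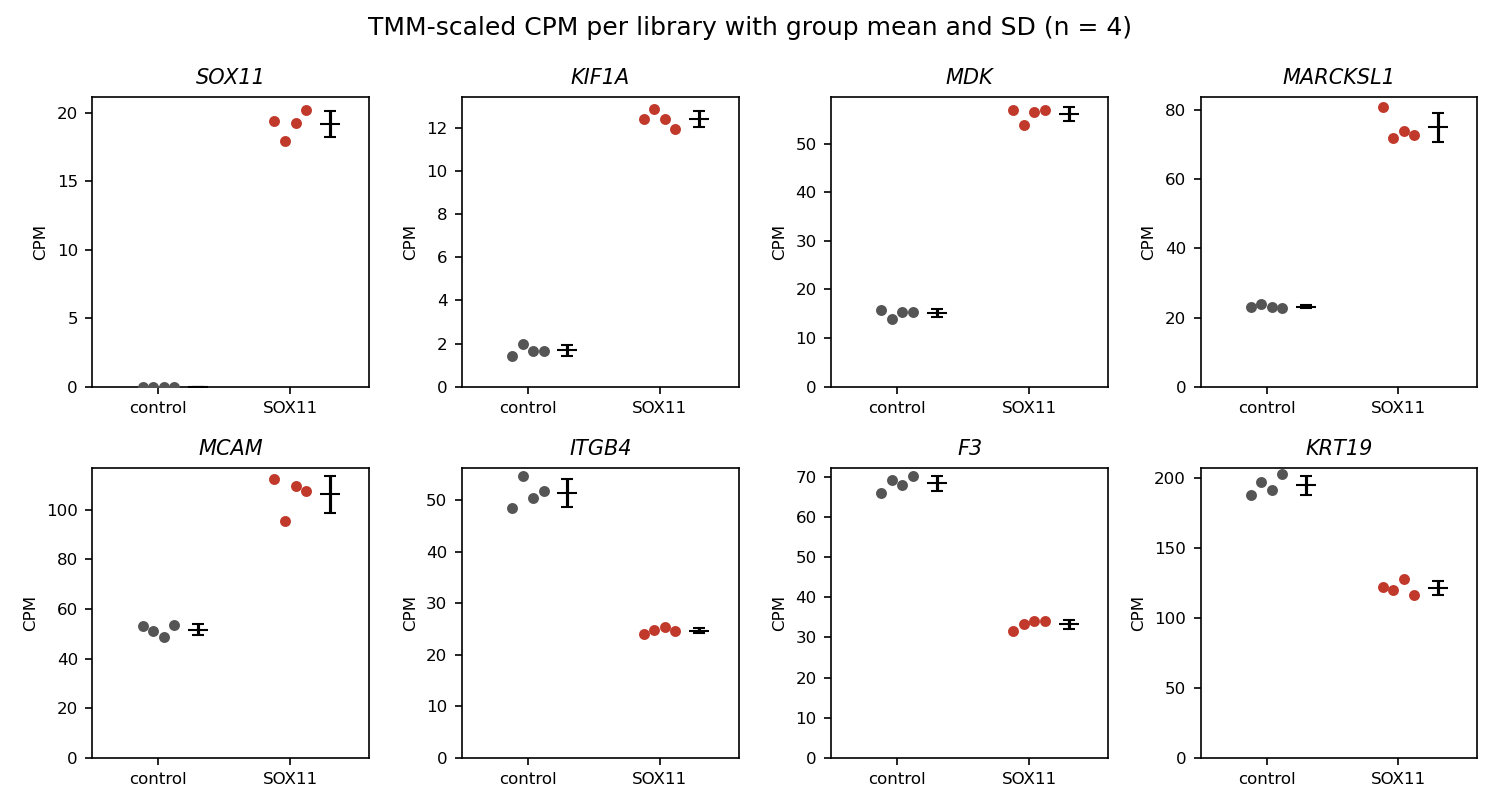
TMM-scaled CPM (y axis, starting at 0) in each control and SOX11 library (points), with the group mean and SD beside them (bar, n = 4). SOX11 was at 0 in the 4 control libraries, and KIF1A rose from 1.68 to 12.4 CPM.

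In SOX11-expressing cells, neuronal genes rose as a list and basal epithelial genes fell. KIF1A, a kinesin motor of axonal vesicle transport, rose from 1.68 ± 0.245 to 12.4 ± 0.373 CPM (log2 fold change 2.87 ± 0.125 SE, edgeR adjusted p = 4.08e-17, n = 4 per group). MDK, the heparin-binding growth factor midkine, rose from 15.1 ± 0.813 to 56.0 ± 1.48 CPM (1.90 ± 0.0560 on the log2 scale). The collagenase gene MMP1 fell from 2.27 ± 0.717 to 0.435 ± 0.186 CPM (log2 fold change -2.38 ± 0.304). ITGB4, the integrin subunit of hemidesmosomes, fell from 51.4 ± 2.66 to 24.7 ± 0.535 CPM (log2 fold change -1.06 ± 0.0527).

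In all, 3130 of 15665 tested genes changed, 1615 higher and 1515 lower. The lower genes were the larger number with DESeq2 (1010 higher and 1228 lower), without a filter on low counts (1499 and 1613) and without SOX11 replicate 2 (1434 and 1440). Most changes were small. The median fold size was 1.18, with 1.24 among the higher genes and 1.14 among the lower ones. At least 2-fold changes were seen in 147 genes, of which 127 were higher and 20 lower. Without a filter on low counts that number was 275, and a test against a 2-fold change called 26. The groups did not overlap in 2498 of the changed genes, and in 21.1% of all tested genes against 2.86% by chance.

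**Figure D2:**
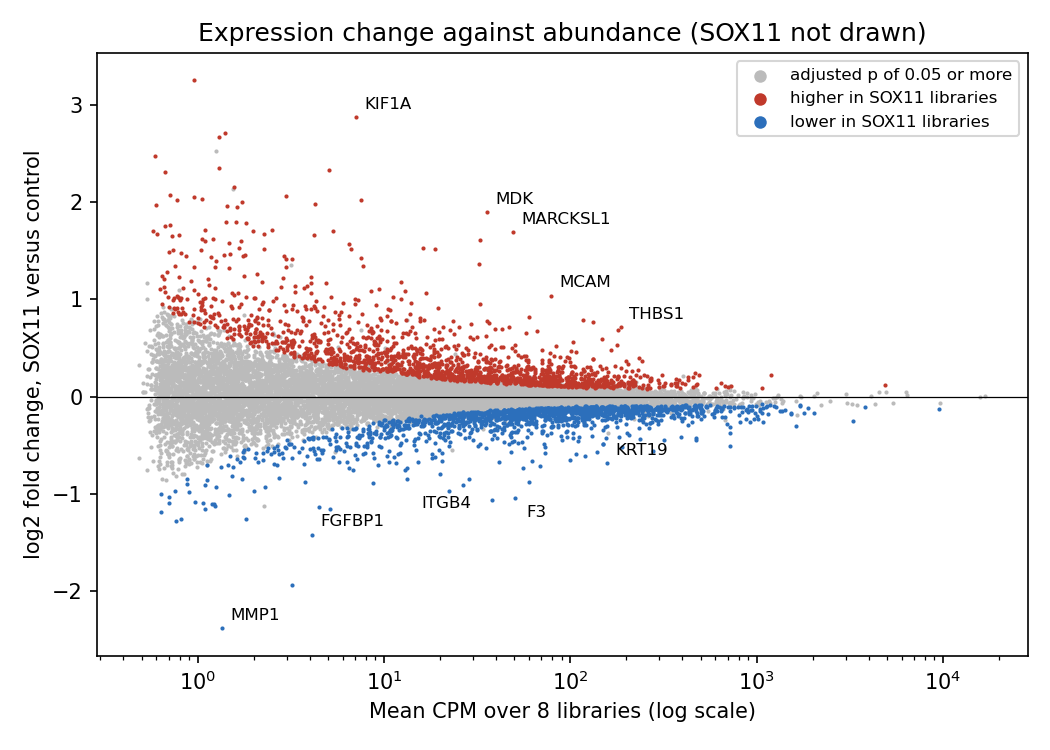
Log2 fold change of each tested gene (y axis) against its mean CPM over 8 libraries (x axis, log scale), with called genes in red (higher) or blue (lower) and SOX11 not drawn. Of the genes changed at least 2-fold, 127 were higher and 20 lower.

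For the other genes with the largest increases, log2 fold changes were 2.71 for GAL3ST4, 2.66 for TMSB15A, 2.35 for ABCA8, 2.33 for SLC6A16, 2.16 for the T-type calcium channel gene CACNA1G, 2.07 for C14orf132, 2.03 for TMEM178B, 2.02 for NELL2, 2.00 for ZC4H2, 1.98 for IGSF9, 1.96 for NKAIN1, 1.95 for RBM20 and 1.80 for LFNG, which encodes a glycosyltransferase acting on NOTCH receptors. SLC6A16 rose from 1.67 ± 0.103 to 8.46 ± 0.626 CPM. Apart from SLC6A16, C14orf132, NELL2 and IGSF9, these genes were below 1 CPM in control, from 0.346 for TMSB15A to 0.706 for LFNG. Their fold sizes are less certain, with an SE from 0.222 (RBM20) to 0.309 (ABCA8). Among decreases, log2 fold changes were -1.94 for LINC01322, -1.42 for FGFBP1, a carrier of fibroblast growth factors, -1.26 for TNS4, -1.16 for KYNU, -1.13 for CCNA1, -1.12 for NMRAL2P, -1.04 for F3, which encodes tissue factor, -0.97 for TBC1D2, -0.93 for RASGRP3, -0.91 for SLC22A31, -0.89 for LETM2 and -0.88 for ABCA1. F3 fell from 68.3 ± 1.85 to 33.3 ± 1.12 CPM. LETM2 overlaps FGFR1 on the opposite strand.

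Neuronal and neurogenesis genes rose as a list (camera adjusted p = 5.64e-07, and adjusted p = 0.0319 with an estimated correlation). Of the 36 listed genes, 19 were tested. Of these, 11 were higher and 0 lower over all genes, and 11 and 1 adjusted over the list alone. MARCKSL1, an actin-regulating protein, rose from 23.1 ± 0.523 to 75.0 ± 4.12 CPM (log2 fold change 1.69 ± 0.0513). The dendritic microtubule protein gene MAP2 (1.43), the actin-binding drebrin gene DBN1 (0.60) and TEAD2 (0.78), which overlaps CD37 on the opposite strand, rose as well. TEAD2 is also among the SOX family and SOXC-linked genes, so it is not particular to the neuronal list. Axon guidance genes were not called as a list (adjusted p = 0.344), with 10 of 33 higher and 5 lower, and 11 and 5 adjusted over the list alone. PLXNB1 (0.77), EFNA5 (0.51) and NTN1 (0.46) rose and NTN4 (-0.42) fell. Neuroendocrine prostate cancer genes were not called (adjusted p = 0.758), with 1 of 11 higher and 2 lower, the same adjusted over the list alone. PEG10 rose by 0.22 and AURKA (-0.24) and UCHL1 (-0.15) fell.

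Basal and squamous epithelial genes fell as a list (camera adjusted p = 2.02e-05, and adjusted p = 0.0495 with an estimated correlation). Of 11 tested members, 6 were lower and 0 higher, and 9 and 0 adjusted over the list alone. Besides ITGB4, the falls included SFN (-0.41) and the hemidesmosome collagen gene COL17A1 (-0.58). Epithelial junction and identity genes moved in both directions and were not called as a list (adjusted p = 0.459), with 8 of 29 higher and 10 lower, and 9 and 11 adjusted over the list alone. The keratin genes KRT19 (-0.68) and KRT18 (-0.42), which overlaps KRT8 on the opposite strand, fell, while plakoglobin (JUP, 0.82) and CLDN1 (0.45) rose. CDH1, which encodes E-cadherin, was at 42.1 ± 4.05 CPM in control and 38.8 ± 6.99 in SOX11 libraries (adjusted p = 0.660). Mesenchymal genes were not called (adjusted p = 0.371), with 3 of 21 higher and 4 lower, and 3 and 5 adjusted over the list alone. FN1 (0.69) and the repressor gene ZEB2 (2.06), at 1.54 CPM in SOX11 libraries, rose, while CD44 (-0.59), MMP14 (-0.34) and vimentin (VIM, -0.23) fell.

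Adhesion receptor genes were not called as a list (camera adjusted p = 0.371), with 7 of 21 higher and 3 lower, the same adjusted over the list alone. MCAM, the melanoma cell adhesion molecule, rose from 51.6 ± 2.23 to 106 ± 7.42 CPM (log2 fold change 1.04 ± 0.0475) and overlaps CBL on the opposite strand. ITGB5 (0.41) and CADM1 (0.31) rose and ALCAM (-0.52) fell. Matrix genes (adjusted p = 0.187) had 11 of 29 higher and 5 lower, and 13 and 8 adjusted over the list alone. THBS1 (0.71), FBLN1 (0.92) and LAMA1 (0.46) rose and EFEMP1 (-0.61) fell. COL1A1, which is also among the fibroblast markers, rose from 3.61 to 6.02 CPM. Proteases and their inhibitors (adjusted p = 0.646) had 3 of 22 higher and 7 lower, and 4 and 7 adjusted over the list alone, with falls in CTSL (-0.40), TIMP1 (-0.38) and ADAM9 (-0.18) besides MMP1. Cytoskeleton and migration genes (adjusted p = 0.162) had 5 of 40 higher and 9 lower, and 7 and 10 adjusted over the list alone. The actin-bundling gene FSCN1 (0.39) rose and MYO10 (-0.30), ACTN1 (-0.19) and MSN (-0.14) fell.

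Antigen presentation genes fell as a list (camera adjusted p = 0.000867, but adjusted p = 0.0642 with an estimated correlation). Of 18 members, 9 were lower and 1 higher, and 11 and 1 adjusted over the list alone. B2M, the light chain of MHC class I, fell from 369 ± 14.8 to 271 ± 15.6 CPM, and TAP2 (-0.35), PSMB8 (-0.50), which overlaps PSMB9, and HLA-E (-0.19) fell. Interferon response genes were lower as a list (adjusted p = 0.0347, but adjusted p = 0.356 with an estimated correlation), with 8 of 28 lower and 1 higher, and 8 and 2 adjusted over the list alone. OAS3 (-0.43), IFIT3 (-0.62), IFIT2 (-0.64) and ISG15 (-0.32) fell. This list's call ended without control replicate 1 (adjusted p = 0.0626), control replicate 3 (0.0728), SOX11 replicate 3 (0.0513) or SOX11 replicate 4 (0.0727). NF-kB and cytokine genes were not called (adjusted p = 0.582), with 5 of 23 higher and 2 lower, and 6 and 3 adjusted over the list alone. CXCL5 (1.52), IL32 (0.52), BIRC3 (0.30) and NFKBIA (0.15) rose.

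Cell cycle genes were slightly lower (camera adjusted p = 1.41e-06, but adjusted p = 0.464 with an estimated correlation). Of 35 members, 21 were lower and 0 higher, and 23 and 0 adjusted over the list alone, with a median log2 fold change of -0.11. CCNB2 (-0.26), BUB1 (-0.22), CDK1 (-0.21) and TPX2 (-0.20) fell. The list's replication genes MCM2 to MCM7 were not called, with log2 fold changes from -0.06 (MCM6) to 0.07 (MCM2). Ribosomal protein genes had a median of -0.10 (adjusted p = 5.82e-09, but adjusted p = 0.356 with an estimated correlation), with 27 of 40 lower and 0 higher, and 31 and 0 adjusted over the list alone. RPLP1 (-0.27), RPS12 (-0.21), RPL4 (-0.17) and RPL27 (-0.16) fell. Their share of all counts was 4.59% to 4.75% in control and 4.37% to 4.51% in SOX11 libraries. Ribosome biogenesis genes (adjusted p = 0.00885, but adjusted p = 0.672 with an estimated correlation) had 7 of 30 lower and 0 higher, the same adjusted over the list alone, with SRM (-0.22), WDR43 (-0.15), DDX21 (-0.14) and NOP56 (-0.14) lower. Without SOX11 replicate 2 this list's adjusted p was 0.125. Nuclear oxidative phosphorylation genes (adjusted p = 0.000489, and adjusted p = 0.0495 with an estimated correlation) had 9 of 36 lower and 1 higher, and 10 and 1 adjusted over the list alone. SDHD (-0.26), CYCS (-0.18), ATP5PB (-0.18) and COX4I1 (-0.14) fell.

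Hypoxia and glycolysis genes were lower as a list (camera adjusted p = 0.00607, but adjusted p = 0.0681 with an estimated correlation), with 14 of 35 lower and 3 higher, and 17 and 3 adjusted over the list alone. The glycolytic genes PKM (-0.25) and PGK1 (-0.20) and the glucose transporter gene SLC2A1 (-0.28) fell, while ADM (1.45), which encodes adrenomedullin, rose. Stress response genes (adjusted p = 0.0347, but adjusted p = 0.672 with an estimated correlation) had 7 of 35 lower and 1 higher, and 8 and 1 adjusted over the list alone, with ATF5 (-0.31), TRIB3 (-0.22), VLDLR (-0.20) and SHMT2 (-0.16) lower. That call ended without control replicate 1 (adjusted p = 0.124), control replicate 3 (0.0638) or SOX11 replicate 4 (0.199). Oxidative stress genes were not called (adjusted p = 0.459), with 3 of 24 higher and 9 lower, and 5 and 9 adjusted over the list alone. HMOX1 (0.65) rose and FTL (-0.26), GCLC (-0.26) and NQO1 (-0.16) fell. Cholesterol and fatty acid genes (adjusted p = 0.601) had 3 of 33 higher and 4 lower, the same adjusted over the list alone, with ACACA (0.16) higher and ELOVL6 (-0.16) lower. The ELOVL6 call ended without control replicate 1 (adjusted p = 0.0576). The p53 and apoptosis genes (adjusted p = 0.715) had 10 of 33 higher and 6 lower, and 10 and 7 adjusted over the list alone. TP53INP1 (1.10) and BMF (1.42) rose and PMAIP1 (-0.39) and FAS (-0.63), which overlaps ACTA2, fell.

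Growth factor and receptor genes were not called as a list (camera adjusted p = 0.582), with 7 of 38 higher and 9 lower, and 9 and 11 adjusted over the list alone. HBEGF (0.74) rose and MET (-0.49) and IGFBP6 (-0.66) fell. TGF-beta and BMP genes (adjusted p = 0.371) had 7 of 24 higher and 5 lower, and 8 and 5 adjusted over the list alone. TGFB2 (0.51) and ID3 (0.29) rose and FSTL3 (-0.48) and TGFBR2 (-0.23) fell. Among WNT genes (adjusted p = 0.582), 4 of 27 were higher and 0 lower, the same adjusted over the list alone: WNT5B (0.79), NKD2 (0.46), FZD3 (0.35) and TCF7L2 (0.17). NOTCH genes (adjusted p = 0.251) had 4 of 22 higher and 1 lower, the same adjusted over the list alone. NOTCH3 (0.57) and HEY1 (1.08) rose and NUMB (-0.12) fell. The HEY1 call ended without control replicate 4 (adjusted p = 0.0717) and with DESeq2 (0.105), and that of NUMB without control replicate 3 (0.0545) or SOX11 replicate 3 (0.0623). SOX family and SOXC-linked genes (adjusted p = 0.0978) had 5 of 12 higher and 1 lower, and 6 and 1 adjusted over the list alone, with BCL6 (0.41) and TCF3 (0.26) higher and PDGFA (-0.64) lower. Without control replicate 1 this list was called higher (adjusted p = 0.0483). Androgen receptor and luminal genes (adjusted p = 0.371) had 2 of 13 higher and 1 lower, the same adjusted over the list alone. CAMKK2 (0.29) and ABCC4 (0.15) rose and NDRG1 (-0.30) fell. The ABCC4 call ended without control replicate 2 (adjusted p = 0.0565) or SOX11 replicate 4 (0.0555).

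Lists that check RNA composition and other cell types were read in the same way. Replication-dependent histone genes rose (camera adjusted p = 0.000308, but adjusted p = 0.356 with an estimated correlation), with 4 of 9 higher and 0 lower, and 7 and 0 adjusted over the list alone. H2BC21 (0.66), H4C8 (0.55), H1-2 (0.25) and H2BC11 (0.35) were higher. The H2BC11 call ended without control replicate 2 (adjusted p = 0.0671) or SOX11 replicate 1 (0.0823) and with DESeq2 (0.0929). Mitochondrially encoded genes were not called (adjusted p = 0.582), with 2 of 13 higher and 0 lower, the same adjusted over the list alone. MT-ND6 (0.13) lost its call without SOX11 replicate 1 (adjusted p = 0.0579) and MT-CYB (0.12) without control replicate 2 (0.0707), control replicate 4 (0.0827) or SOX11 replicate 2 (0.0610). Immediate early and heat shock genes (adjusted p = 0.758) had 4 of 25 higher and 5 lower, the same adjusted over the list alone, with NR4A2 (0.96) and NR4A1 (0.45) higher and IER5 (-0.41) and HSPA8 (-0.17) lower.

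Fibroblast markers were higher as a list of 3 tested genes (camera adjusted p = 0.0425, but adjusted p = 0.356 with an estimated correlation), with 2 higher and 0 lower, and 3 and 0 adjusted over the list alone. COL1A1 rose from 3.61 ± 0.890 to 6.02 ± 0.847 CPM and SFRP4 from 0.355 ± 0.326 to 1.11 ± 0.105 CPM. The SFRP4 control value rested in part on control replicate 3, at 0.824 CPM, and its log2 fold change was 1.65 with that library and 2.39 without it. This list's call ended without SOX11 replicate 1 (adjusted p = 0.0687), SOX11 replicate 2 (0.0652) or SOX11 replicate 4 (0.0727), with length and GC offsets chosen after seeing the data (0.0503), and under the stricter filter, which left too few members. Markers of the HEK293 line (adjusted p = 0.582) had 1 of 7 higher and 0 lower, the same adjusted over the list alone. SALL2 (0.21) lost its call in 4 of 8 fits with a library left out, with an adjusted p of 0.0789 without control replicate 1, 0.0624 without control replicate 2, 0.0741 without SOX11 replicate 2 and 0.110 without SOX11 replicate 3, and with DESeq2 it was 0.109. Endothelial and blood markers had 2 tested members each and were not tested as lists. EGFL7 (-0.21) fell, and its call ended without control replicate 2 (adjusted p = 0.109), control replicate 4 (0.0899), SOX11 replicate 2 (0.0512) or SOX11 replicate 4 (0.0820) and with DESeq2 (0.0854). Of the blood markers 0 were called, and 1 was higher adjusted over the list alone. The most abundant, CORO1A, which is also among the cytoskeleton genes, was at 5.19 CPM over all libraries.

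**Figure D3:**
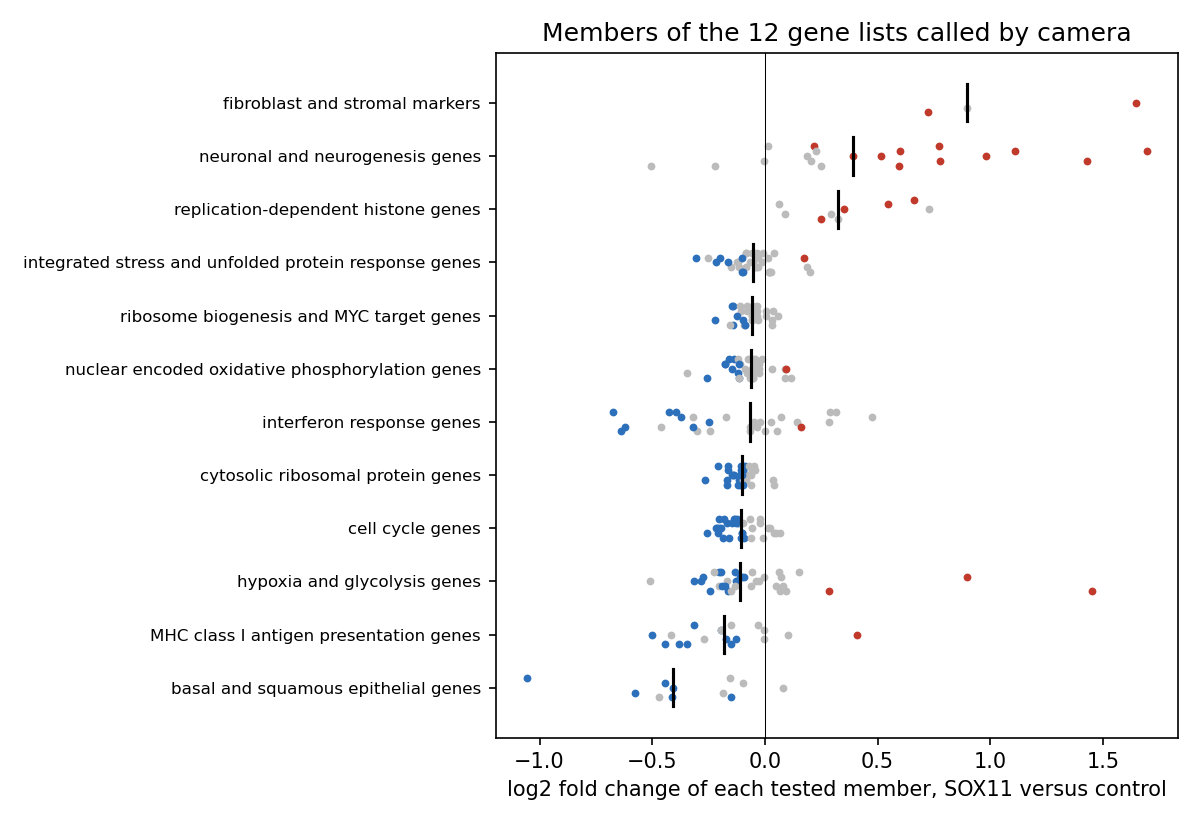
Log2 fold change (x axis) of each tested member of the 12 lists called by camera (rows), in red or blue where called and grey where not, with the list median as a vertical bar. Neuronal members had a median of 0.39 and basal members of -0.41, while the ribosomal protein median was -0.10.

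Of the 33 lists tested, 12 were called by camera, 3 higher and 9 lower, and 3 of them (neuronal, basal and oxidative phosphorylation) with an estimated correlation. The number of called lists is not set apart from chance, because 2 of the 35 splits of the libraries into groups of 4, the real one included, called 12. In 9 lists, 0 of them called, the median, the mean and the test differed in sign (mesenchymal, epithelial, neuroendocrine, NF-kB, adhesion, protease, growth factor, oxidative stress and immediate early genes).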

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

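The counts of splits per list and per kind of split were chosen after their results were seen, and the other tests before their own results were. Of the 35 splits of the 8 libraries into 2 groups of 4, only the real one reached 3130 changed genes. The highest other split had 1. For genes changed at least 2-fold, 1 of 35 reached 147 and the highest other had 0. No split can be rarer than 1 of 35. Every other split mixes the groups, so the real difference adds to its spread within sides and few genes are called. These counts therefore cannot by themselves exclude chance. For gene lists, 2 of 35 reached 12 and the highest other also had 12, so chance is not excluded for that number. In 16 of the 34 other splits each side held 3 libraries of a group and 1 of the other, which keeps part of the real difference, and these called 4 to 10 lists. In the 18 splits with 2 libraries of each group on each side, 11 called at least 1 list, with a median of 2. Of the 12 called lists, 5 had their smallest p in the real split (neuronal, basal, antigen presentation, hypoxia and oxidative phosphorylation). Those lists and the fibroblast markers were called in 0 of the 18 splits, histone genes in 1, ribosomal protein and interferon genes in 2, cell cycle and stress response genes in 6 and ribosome biogenesis genes in 7. In these splits a list's difference between the groups adds to the spread within sides. A low count is thus partly fixed in advance and does not mark a list as firmer. In the 16 splits that keep part of the difference, the neuronal and oxidative phosphorylation lists were called in 12, the basal list in 9, antigen presentation in 8 and hypoxia in 5. A difference in culture or handling between the groups cannot be separated from SOX11 in this design.

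Changes of at least 1.5-fold were mostly increases (379 of 470, 80.6%). Genes near 0 in the controls have more room to rise than to fall. Among genes with a mean of at least 10 CPM, 69.6% were higher (64 of 92, 95% Clopper-Pearson interval 59.1% to 78.7%), and below 10 CPM 83.3%. The interval counts genes as independent and does not measure the spread between libraries, so it is too narrow if genes move together. In these libraries rises outnumbered falls above 10 CPM too, which argues against low counts as the whole cause of the excess seen here. Library scaling would need an offset of 0.18 (log2) to even out the split, and the scalings differed by 0.0089 at most. All of them centre the bulk of genes near 0, with medians from -0.00093 (RLE) to 0.0080 (upper quartile). Their closeness therefore cannot show an offset that they share. The fold changes are relative to the bulk of genes in each library and do not measure total RNA. That SOX11 raised more genes by 1.5-fold than it lowered may remain as a hypothesis for relative levels, with culture differences open.

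Ribosomal protein, ribosome biogenesis, oxidative phosphorylation and cell cycle genes had a median log2 fold change of -0.095 over 141 members, of which 64 were called lower and 1 higher. With an estimated correlation the call was kept for oxidative phosphorylation (adjusted p = 0.0495) and lost for ribosomal protein (0.356), cell cycle (0.464) and ribosome biogenesis genes (0.672). With length and GC offsets per library the median was -0.086 (bootstrap 95% interval -0.098 to -0.075), so the offsets left most of the shift. The bootstrap drew genes as if independent and did not draw libraries. Estimated correlations were 0.386 for cell cycle, 0.378 for ribosomal protein, 0.493 for ribosome biogenesis and -0.0020 for oxidative phosphorylation genes. The interval is therefore too narrow and does not measure the spread between libraries. Of the 18 splits with 2 libraries of each group on each side, ribosome biogenesis genes were called in 7, cell cycle genes in 6, ribosomal protein genes in 2 and oxidative phosphorylation genes in 0, so the first 3 lists also moved apart from the group difference in some splits. Slower growth with SOX11, or a difference in cell density, could give the same pattern, and neither was tested. The fall in cell cycle genes did not extend to the replication genes MCM2 to MCM7, which were not called.

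A library stood far from the other 3 of its group in 17 of the 314 sets of 4 values tested, and chance flags about 1 in 20. SOX11 replicate 2 held 9 of the 17. Its mitochondrial share was 9.35% (others 8.73% to 8.80%) and the share of its 10 most counted genes 8.89% (8.29% to 8.38%). In that library, ABCA1 was at 3.37 CPM (others 2.37 to 2.48), ACTN1 at 416 (458 to 466), MDK at 53.8 (56.4 to 56.9), MT-CYB at 5429 (4992 to 5014), NKD2 at 10.5 (12.5 to 12.7), SDHD at 57.3 (lowest of the others 52.5) and SRM at 91.9 (102 to 104). In SOX11 replicate 1, CACNA1G was at 3.27 CPM (others 2.25 to 2.41) and JUP at 85.9 (72.5 to 74.6). TPX2 was at 368 CPM in SOX11 replicate 4 (349 to 351). Among controls, ABCA1 was at 5.91 CPM in replicate 3 (4.49 to 4.71) and TGFBR2 at 138 (128 to 129), FN1 at 27.3 in replicate 2 (31.1 to 31.4) and PDGFA at 4.22 (5.75 to 5.97), and UCHL1 at 906 in replicate 1 (861 to 865).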

How the results depend on the processing

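The length and GC offsets were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 3130 under every alternative run (2238 with DESeq2 to 3527 with length and GC offsets, and 2466 to 3057 with 1 library left out), and SOX11 kept its call in each. DESeq2 called 1010 genes higher and 1228 lower, no filter gave 1499 and 1613, and leaving out SOX11 replicate 2 gave 1434 and 1440, against 1615 and 1515, and the cause was not tested. Genes changed at least 2-fold numbered 275 with no filter, where more low-count genes are tested, and 26 in the glmTreat test, which is a stricter test by construction. With an estimated correlation 3 lists were called instead of 12. Antigen presentation and hypoxia genes lost their calls although their estimated correlations, 0.0038 and -0.0032, were below the preset 0.01. A higher correlation is therefore not why those calls ended. The unadjusted camera p also rose for the neuronal list (3.42e-08 to 0.000967, estimate -0.021). It rose for oxidative phosphorylation genes too (8.90e-05 to 0.00388, estimate -0.0020). The refit thus gave larger p even where the correlation was lower, so a lost call does not by itself mark correlated genes. The other lists that lost their calls had estimates from 0.049 (interferon) to 0.493 (ribosome biogenesis), and the cause was not tested. Upper quartile scaling gave 1720 higher and 1385 lower genes. No pairing by replicate number was seen: correlations of same-numbered deviations were 0.0632, -0.0683, -0.0412 and 0.109, and not every library correlated best with its own number. Counting noise in low-count genes pulls such values toward 0, so a weak shared effect cannot be excluded. With the replicate block 2899 genes changed, 151 at least 2-fold, SOX11 had a fitted log2 fold change of 11.26 (a value that depends on the prior count) and 11 lists were called, without the interferon list (adjusted p = 0.0715). Uncalled lists changed direction with 1 library left out, with adjusted p from 0.280 to 0.965 for cholesterol, 0.351 to 0.913 for NF-kB, 0.187 to 0.993 for mitochondrial and 0.478 to 0.993 for immediate early genes, and the cause was not tested. Of 149 called genes besides SOX11, those taken by the naming rule and VIM, 140 kept their call in all 8 such fits and 0 changed sign. The naming rule picked genes by small p or large change in the same libraries, so this share does not hold for calls in general. Of all 3130 calls, 2358 were kept without control replicate 2, the fewest of these fits, and 2702 without control replicate 1, the most. DESeq2 kept 2202. Fry, which does not compare a list with other genes, called 18 lists, 10 higher and 8 lower. It did not call stress response (adjusted p = 0.135) or ribosome biogenesis genes (0.182), and it called 8 lists that camera did not: SOX family (0.00603), matrix (0.00854), TGF-beta and BMP (0.0281), NOTCH (0.0300), WNT (0.0328), adhesion receptor (0.0474) and axon guidance genes (0.0485) higher, and epithelial genes (0.0485) lower. DESeq2 did not call EGFL7, H2BC11, HEY1 or SALL2. For SOX11 versus control, edgeR was run on simulated counts at this depth and number of libraries, on 15473 genes. It gave back 77.2% of 1.5-fold changes and fewer of the smaller ones. Other depths and larger numbers of changed genes were not tested.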

Other observations

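The grouping of genes by the stem of their symbol was chosen after seeing the data. Of 151 such families with at least 10 tested genes, 9 were called by camera, 2 higher and 7 lower, and 0 with an estimated correlation (lowest adjusted p = 0.363, and 15 families with an unadjusted p below 0.05). The zinc finger genes named ZNF had 55 of 455 members higher and 11 lower (camera adjusted p = 0.0384), and the histone demethylase genes named KDM had 5 of 18 higher and 0 lower (0.0443). Mitochondrial ribosomal protein genes named MRPL had 11 of 49 lower and 0 higher (0.000561), translation initiation factor genes named EIF 14 of 66 lower and 2 higher (0.00674), and the chaperonin genes named CCT 5 of 10 lower and 0 higher (0.0384). Keratin genes and pseudogenes named KRT had 5 of 18 lower and 0 higher (0.0384). Genes named RPL, which include pseudogenes, had 26 of 164 lower and 0 higher (0.000561). Those named RPS, which also include pseudogenes and kinase genes such as RPS6KB1, had 23 of 94 lower and 1 higher (0.000561), and the small nucleolar host genes named SNHG 7 of 24 lower and 0 higher (0.0384). These calls rest on the preset correlation, and whether other splits of the libraries call these families was not tested.

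SOX11 was the 1 gene with 0 counts in every control library and at least 3 counts in every SOX11 library. In the opposite direction there was also 1 gene, ENSG00000228802, which has no symbol in the name table, with 23 counts over the control libraries and 0 over the SOX11 libraries. It was chosen after its values were seen.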
